A study of Mus musculus with 2 samples.

How the data were processed

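RNA of mutant and control ureters of mouse embryos was compared on 2 two-colour arrays, each with 150 ng of total RNA as labelling input per the labels' protocols. Each array carried 174979 spots, with each of 39429 probes printed 4 times. The arrays were scanned and quantified with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes, and the probe design was annotated on mm9, per the file headers. The mean and local background signals of the spots are intensity values without normalization, per the file headers. The deposited processed signals are intensity values after background subtraction, detrending and LOWESS dye normalization with surrogate values for dim spots, per the file headers. The authors' deposited table of the whole series holds 1 score per probe and array, a signed linear fold whose steps are not given in the sources used here. Set against the scanner values, its sign was found to be mutant over control on both arrays (correlation with the processed signals across tested probes 0.973 and 0.991), its column medians were 1, and its centring stays unknown. Both arrays were on 1 slide, so no slide effect could be tested.

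The background was corrected with normexp (offset 50) and each array normalised with loess (span 0.3, control spots at weight 0) in limma 3.58.1 under R 4.3.3. Spots with an outlier flag (3.35% and 3.05%) were left out and the spots of a probe averaged. The ratio of array 2 was turned, so that every ratio is mutant over control. A probe was tested if a share of more than 0.5 of its spots were well above background in the mutant channel on both arrays or in the control channel on both, which kept 27493 probes. A gene was represented by its brightest tested probe, and 5165 of 20923 genes had more than 1. Gene names were updated through unversioned RefSeq accessions of the GRCm38.p6 assembly's gene table, which matched 28328 of 39429 probes, and the name of the array design was kept otherwise. No coordinates were taken from that table.

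Genes were tested with lmFit and eBayes on the turned ratios against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2 arrays leave 1 residual degree of freedom, with 6.32 prior degrees of freedom from all genes. Since nothing says how many embryos a pool held, the p-values measure the spread between these 2 arrays. The 26 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. With an estimated correlation, camera rests on the 1 residual degree of freedom, so almost no list can pass. The leukocyte list's estimated correlation was -0.042, below the preset one, yet its camera p went from 1.1e-27 to 0.053. An adjusted p with an estimated correlation therefore cannot decide whether a list's call holds. The estimates of the FGF and ERK, immediate early and skeletal muscle lists were also below the preset one (-0.029, -0.042 and -0.055). The other called lists had estimates above it, from 0.030 to 0.62, with 0.24 for hedgehog and 0.62 for erythroid genes. For those lists the preset correlation may be too low and the camera p too small. The lists, the tests, the rule for named genes and the alternatives, apart from those named last, were fixed before the data were examined. The text names all probes of Fgfr1 and Fgfr2, the 12 largest rises and falls at least 1.5-fold the same way on both arrays (called genes first), the called members of each list (at most 8) or otherwise members among the 4 with the largest mean ratio, and sex-linked genes. Clone, predicted-gene and probe names were counted and not named. Levels per channel are log2 values after loess and Aquantile normalization, and the percentages of Xist were taken on the linear scale with the offset subtracted.

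The gene and list tests were run on simulated data, 20 sets of 20923 genes with spreads drawn from the prior fitted to the real genes and 100 genes planted at each fold. For the comparison of mutant and control, 72.2% of genes planted at 2-fold and 99.6% at 4-fold were called, and 9.41% of calls were unchanged genes, above the nominal share. The many planted genes ease the Benjamini-Hochberg threshold, so the shares of planted genes called do not carry over to data with few calls. That does not account for the excess of unchanged genes among the calls, so adjusted p values in the real data may also be too small. In the real data 6 genes were called, and Hoxb8 missed the limma threshold at a 2.92-fold difference (adjusted p = 0.0515). In these sets, on average 56.5 unchanged genes differed at least 1.5-fold the same way and 58.6 genes in opposite ways. The simulated spread was fitted to the difference between the 2 arrays, so it holds any dye or sex difference beside noise. It was also the same for both arrays, whose ratios had an SD of 0.208 and 0.325. No list was called without a planted shift (mean 0). Genes were simulated as independent of each other, so this does not show how often lists whose members move together are called falsely.

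Alternatives were no background correction, a normexp offset of 16, the processed signals, median centring, Aquantile, other filters on dim probes, the mean of a gene's probes, 1 test per probe, an intensity trend, robust eBayes, the 4 channels as separate samples with no replicate block, the authors' table, saturated probes left out, a threshold of 2-fold, and each array alone. Lists of hepatocyte, granulocyte and spermatid genes, and the removal of other tissues' marker genes, were chosen after seeing the data.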

Results

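The data were 2 two-colour Agilent microarrays of ureters dissected from mouse embryos of the NMRI strain at stage E13.5. Each array hybridised RNA of a mutant pool and RNA of a control pool together. The mutant ureters carried the Pax2-cre transgene with 2 floxed alleles of Fgfr2, a receptor for fibroblast growth factors, and the control ureters carried floxed alleles without the transgene. The labels give 1 allele of Fgfr1 in both pools as floxed and the other as unspecified, so the mutant pools can differ in Fgfr1. Array 1 held female pools with the mutant RNA in Cy5 and the control RNA in Cy3. Array 2 held male pools with the dyes exchanged. The comparison asks which transcripts differ in the ureter when Fgfr2 is deleted in cells with the Cre. Of 39429 probes, 67.9% to 77.0% were well above background in each channel, no spot was saturated, and 20923 genes were tested. The number of arrays limits the precision. All ratios below are log2 mutant over control, given for array 1 and array 2 or as mean ± SD (n = 2 arrays), and positions are on mm9 as the array design gives them.

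The targeted gene was not lower in the mutant pools at the probes on the array. The 2 probes of Fgfr2 overlap on chromosome 7, from 137307455 to 137307532. The brighter one had ratios of 0.27 and 0.06, and the other had 0.08 and 0.09. The position of the floxed segment is not given in the sources used here, and probes outside the deleted part would check nothing. The 3 probes of Fgfr1 differed among themselves, with ratios of 0.27 and -0.44, 0.03 and 0.51, and 0.17 and -0.16. None of the 5 probes passed the limma test, and their lowest unadjusted p was 0.160.

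The sex labels were compared with Xist, the RNA of the inactive X chromosome, and with Y-linked genes. The brighter Xist probe was at 12.42 in both channels of the female array on the normalised log2 scale. On the male array it was at 8.39 in the mutant and 10.00 in the control channel, so that its ratio was -1.60, and the other Xist probe gave -1.23. On the female array the same probes had ratios of -0.0037 and 0.034. Ddx3y was 10.8-fold and Eif2s3y 8.14-fold higher on the male array than on the female array. The 2 Uty probes and the Kdm5d probe were well above background on the male array alone. Mutant over control, Ddx3y had ratios of -0.29 and 0.31 and Eif2s3y of -0.15 and -0.30.

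Few single genes passed the test, and those that did were higher in the mutant pools. Prm1, a protamine that packs DNA in sperm heads, rose by 3.36 ± 0.81, a 10.2-fold difference. S100a9 and S100a8, calcium-binding proteins abundant in neutrophils, rose by 2.21 ± 0.32 and 2.02 ± 0.064. Cstdc5 and Stfa1, members of the stefin family of cysteine protease inhibitors, rose by 1.92 ± 0.087 and 1.79 ± 0.032. The adjusted p was 0.0172 for Stfa1 and 0.0140 for the other 4. The Prm1 probe lies on chromosome 16 from 10796450 to 10796509, and the S100a9 probe on chromosome 3 from 90496573 to 90496632. The stefin genes form a family of near-identical copies on chromosome 16, so their probes can share transcripts.

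In all, 6 of 20923 genes passed an adjusted p of 0.05 in limma, all 6 higher in the mutant, and 1 of them has no gene symbol. At an unadjusted p under 0.05 there were 845 genes, where 1046 are expected with no effect. By the rule of size, 82 genes differed at least 1.5-fold the same way on both arrays, 62 higher and 20 lower in the mutant, and 20 genes differed at least 1.5-fold in opposite ways. With array 2 left unturned, where the dye and the sex of the pools act together, 0 genes passed limma's adjusted p and 986 had an unadjusted p under 0.05. Across genes, which are not independent replicates, the ratios of the 2 arrays had a Pearson correlation of -0.024 and a Spearman correlation of -0.13. The number of calls in limma was 0 after median centring instead of loess, without the filter on dim probes, and with the 4 channels fitted separately (853, 1076 and 428 genes at an unadjusted p under 0.05), and Prm1 also missed the threshold with the mean of each gene's probes (adjusted p = 0.0553) and in the authors' table (adjusted p = 0.0558). The count of 82 was 78 after median centring, 41 higher and 37 lower, 231 with the processed signals and 208 in the authors' table. Simulated sets gave 56.5 unchanged genes the same way and 58.6 in opposite ways, with a spread that holds any difference between the arrays.

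**Figure D1:**
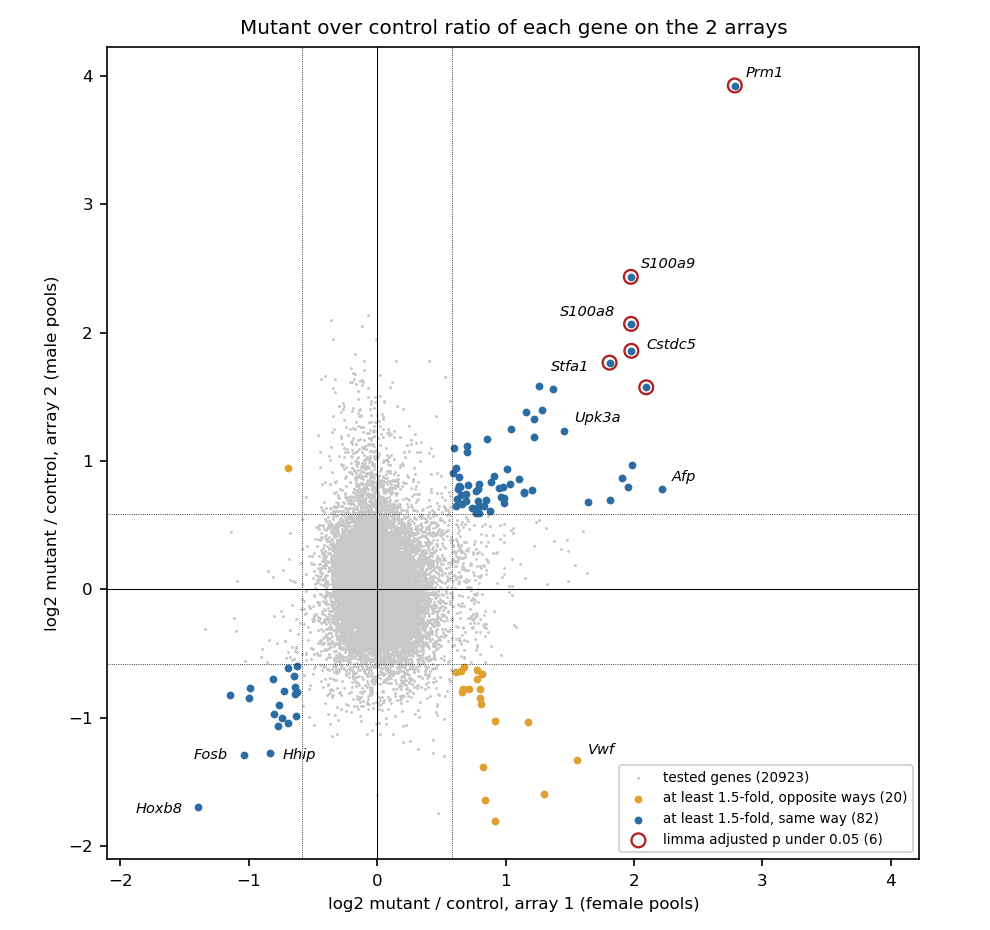
Each point is a tested gene, with its log2 mutant over control ratio on array 1 on the x axis and on array 2 on the y axis, and dotted lines at 1.5-fold. The 82 blue genes differed at least 1.5-fold the same way on both arrays, the 20 orange genes in opposite ways, and the 6 circled genes passed an adjusted p of 0.05 in limma.

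Among genes lower on both arrays, the largest difference was that of Hoxb8, a homeobox gene of body patterning, at -1.55 ± 0.21 (adjusted p = 0.0515). Its probe lies on chromosome 11 from 96146576 to 96146635. Fosb and Fos, immediate early transcription factors, were at -1.17 ± 0.18 and -0.92 ± 0.11, and Egr1, another immediate early gene, was at -0.87 ± 0.18. Hhip, a hedgehog-binding protein induced by hedgehog signalling, was at -1.05 ± 0.32, and its dimmer probe at -0.32 ± 0.16. Mia, Prr7, Nhlrc4, Kcnj16, Hkdc1, Tfap2b and Sel1l3 lay between -0.92 and -0.75. Adjusted p values of these genes ran from 0.0515 to 0.538, so no gene was called lower, although Hoxb8 passed under 3 alternatives (adjusted p = 0.0155 to 0.0320). Among genes higher on both arrays that missed the threshold, Upk3a, a uroplakin of the urothelial surface, was at 1.35 ± 0.15 (adjusted p = 0.0708) and passed under 3 alternatives (adjusted p = 0.0319 to 0.0432). Stfa3, Cstdc4 and Stfa2l1 were at 1.46 ± 0.14, 1.42 ± 0.23 and 1.34 ± 0.083, and each passed under 6 alternatives (adjusted p = 0.0104 to 0.0455). Afp, a fetal liver protein, was at 2.22 on array 1 and 0.78 on array 2, and the liver-made protease inhibitors Serpina1a and Serpina1c were at 1.99 and 0.97, and 1.91 and 0.87. The Serpina1 genes are near-identical copies, and the second Serpina1a probe was at 0.55 ± 0.42.

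Targets of FGF and ERK signalling and immediate early genes were lower in the mutant as groups. Of 21 measured FGF and ERK targets, 14 were lower and 1 higher on both arrays, against 21.4% and 22.1% of all genes. Spry1 and Spry2, feedback inhibitors of receptor tyrosine kinases, were at -0.78 ± 0.40 and -0.58 ± 0.29, and Spred2 at -0.57 ± 0.26. The list median was -0.22 (camera adjusted p = 2.18e-07; adjusted p = 0.541 with an estimated correlation). No member passed over all genes, and Egr1 and Spry1 passed adjusted over the list alone. Of 20 immediate early and heat shock genes, 14 were lower on both arrays, with a median of -0.25 (camera adjusted p = 2.16e-09; adjusted p = 0.541 with an estimated correlation). Again no member passed over all genes, and Fosb, Fos, Egr1, Egr2 and Nr4a1, the last named after its values were seen, passed adjusted over the list alone. Egr1 and Ier3 are in both lists, so the lists are not fully separate evidence. On the same arrays the leukocyte, erythroid and skeletal muscle markers had medians of 0.67, 0.58 and 0.41. The list of FGF receptors and ligands was not called (median -0.059, 0.014 on array 1 and -0.11 on array 2, adjusted p = 0.0878), and Fgf9 in it was at -0.56 ± 0.093.

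Genes of the ureteric epithelium were lower as a group, and urothelial genes went both ways. Of 35 measured epithelial genes, 24 were lower and 4 higher on both arrays, with a median of -0.22 (camera adjusted p = 4.06e-09; adjusted p = 0.541 with an estimated correlation). Elf5 was at -0.61 ± 0.021, Lama5 at -0.35 and -0.84, and Ehf at -0.12 and -1.03, with -0.36 and -0.41 at its dimmer probe. Grhl3, an epithelial transcription factor, was at 0.53 ± 0.17. The ureteric tip list had 9 of 15 genes lower and 0 higher on both arrays, with a median of -0.22 (-0.30 on array 1 and -0.10 on array 2; camera adjusted p = 5.83e-05; adjusted p = 0.541 with an estimated correlation). Etv4 in it was at -0.64 and 0.055, with -0.37 and -0.088 at its dimmer probe. These lists were lower on the arrays on which leukocyte markers were higher (median 0.67). No epithelial gene passed over all genes or adjusted over the list alone, and of the tip list Spry1 passed adjusted over the list alone. Spry1, Etv4, Etv5, Cxcr4 and Dusp6 are in both the tip list and the FGF and ERK list, so these lists are not separate evidence. The list of urothelial differentiation had 8 of 16 genes higher and 5 lower on both arrays and was not called (median 0.057, 0.14 on array 1 and -0.0079 on array 2, adjusted p = 0.246). Adjusted over the list alone, Upk3a, Upk1b (0.52 ± 0.037) and Grhl3 passed as higher and Shh passed as lower, and none passed over all genes.

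Hedgehog and WNT genes and genes of the ureteric mesenchyme were lower as groups by small amounts, and BMP genes were called lower with a median near 0. Shh, the hedgehog ligand made by the ureteric epithelium, was at -0.54 ± 0.13, and its receptor and target Ptch1 at -0.36 ± 0.20, with -0.71 ± 0.63 at the dimmer probe. Foxf1, a mesenchymal target of hedgehog signalling, was at -0.73 ± 0.12, and its dimmer probe at -0.21 ± 0.14. The hedgehog list had 11 of 21 genes lower and 2 higher on both arrays, with a median of -0.11 (-0.016 on array 1 and -0.21 on array 2; camera adjusted p = 0.000283; adjusted p = 0.574 with an estimated correlation). Hhip and Foxf1 passed adjusted over the list alone, and no member passed over all genes. Gli1 and Bmp4, named after their values were seen, were at 0.17 and -0.62, and at -0.042 and -0.46.

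Of 22 BMP genes, 6 were lower and 2 higher on both arrays, against 21.4% and 22.1% of all genes. Their median was -0.038 (-0.019 on array 1 and -0.10 on array 2, camera adjusted p = 0.0277, adjusted p = 0.541 with an estimated correlation). Bmp7 was at -0.53 ± 0.016, and the probes of Bmpr1b differed, at -0.45 ± 0.17 and 0.015 ± 0.42. The BMP call was lost under 5 alternatives. Of 24 WNT genes, 12 were lower and 1 higher on both arrays, with a median of -0.12 (-0.10 on array 1 and -0.32 on array 2, camera adjusted p = 0.000192, adjusted p = 0.541 with an estimated correlation). Wnt7b at -0.49 ± 0.19 and Wnt9b at -0.42 ± 0.0012 were among the lower ones, and Notum was the higher one, at 0.16 and 0.81. The mesenchymal list had 12 of 20 genes lower on both arrays, with a median of -0.21 (-0.12 on array 1 and -0.31 on array 2; camera adjusted p = 8.34e-05; adjusted p = 0.541 with an estimated correlation), among them Tbx3 at -0.44 ± 0.092 and Tbx2 at -0.36 ± 0.44. Leukocyte markers were higher beside these lists and the hedgehog list (median 0.67). No member of these 3 lists passed over all genes, and adjusted over the list alone only Foxf1 of the mesenchymal list passed. Foxf1 and Ptch1 of the mesenchymal list are also in the hedgehog list. Aldh1a3, which makes retinoic acid, was at -0.76 ± 0.33 and passed adjusted over its list alone, in a retinoic acid list that was not called (median -0.073, 0.041 on array 1 and -0.065 on array 2, adjusted p = 0.456). That list had 4 genes higher and 4 lower on both arrays, with Rbp4 at 0.52 ± 0.050 and Rdh10 at 0.46 ± 0.16 among the higher ones.

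**Figure D2:**
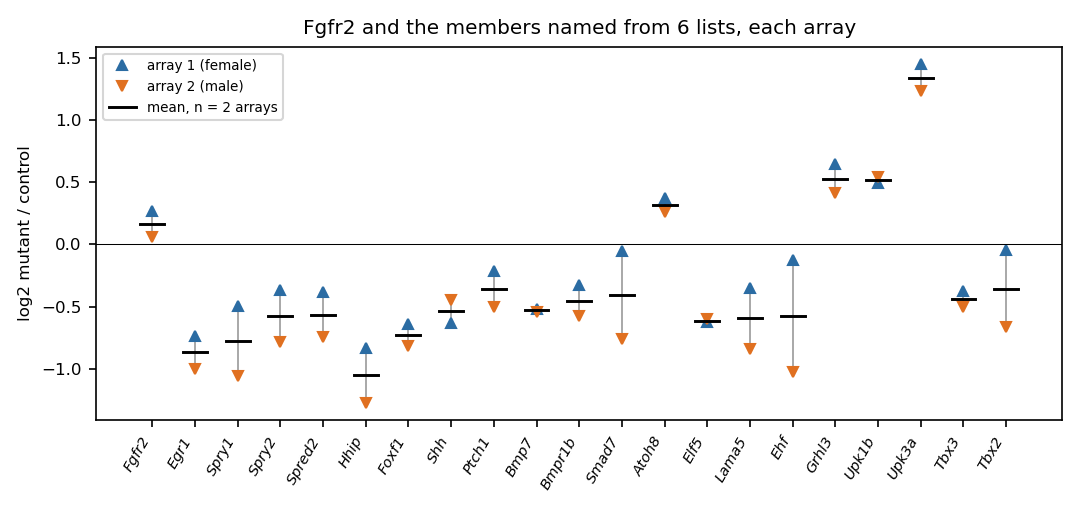
Log2 mutant over control ratios of Fgfr2 and of the members named from 6 lists (FGF and ERK, hedgehog, BMP, ureteric epithelium, urothelial, ureteric mesenchyme), with array 1 and array 2 as triangles and the mean as a bar. Hhip at -1.05 and Upk3a at 1.35 are the extremes, and Fgfr2 is at 0.16.

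Markers of blood, muscle and nerve cells were higher in the mutant pools on the same arrays as the lists above. Of 20 macrophage and leukocyte genes, 17 were higher and 0 lower on both arrays, with a median of 0.67 (camera adjusted p = 2.87e-26; adjusted p = 0.541 with an estimated correlation). S100a8 and S100a9 passed over all genes, and 14 members passed adjusted over the list alone. Of 20 erythroid genes, 15 were higher on both arrays, with medians of 0.78 on array 1 and 0.19 on array 2 (camera adjusted p = 4.27e-15; adjusted p = 0.541 with an estimated correlation), and 11 passed adjusted over the list alone. The adult and embryonic globin genes are similar copies, and Hba-a2 was at 1.48 and 0.38. Of 14 skeletal muscle genes, 10 were higher on both arrays, with a median of 0.41 (camera adjusted p = 2.54e-11; adjusted p = 0.541 with an estimated correlation), and 7 passed adjusted over the list alone, among them Myog at 0.86 ± 0.034. Of 20 neuronal and neural crest genes, 14 were higher on both arrays, with a median of 0.31 (0.32 on array 1 and 0.18 on array 2; camera adjusted p = 6.90e-07; adjusted p = 0.541 with an estimated correlation), and Sox10 was at 0.075 and 1.22. The gonad, adrenal and germ cell list had 5 of 12 genes higher and 0 lower on both arrays, with a median of 0.13 (0.27 on array 1 and 0.059 on array 2; camera adjusted p = 0.0167; adjusted p = 0.541 with an estimated correlation), with Hsd3b1 at 1.11 and 0.19. The gonad call was lost with probes well above background in both groups (adjusted p = 0.0734). No neuronal or gonad gene passed adjusted over its list alone. Apart from the S100 genes, no member of these 5 lists passed over all genes.

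Cholesterol synthesis genes were lower as a group, and the remaining lists were not called. The cholesterol list had 13 of 20 genes lower and 0 higher on both arrays, with a median of -0.16 (-0.16 on array 1 and -0.044 on array 2; camera adjusted p = 3.62e-05; adjusted p = 0.541 with an estimated correlation), and Stard4 was at -0.44 ± 0.46. Leukocyte, erythroid and skeletal muscle markers were higher beside it (medians 0.67, 0.58 and 0.41). Smooth muscle genes had a median of 0.0033 (0.11 on array 1 and -0.045 on array 2, adjusted p = 0.753), with Acta2, smooth muscle actin, at 0.99 and 0.17, Tnnt2 at 0.56 ± 0.085 and Synpo2 at -0.58 ± 0.20, with -0.11 ± 0.065 at its dimmer probe. Myocd, a regulator of smooth muscle genes named after its values were seen, was at 0.14 and -0.83. Fibroblast and matrix genes had a median of 0.083 (0.20 on array 1 and 0.020 on array 2, adjusted p = 0.127), with Igf1 at 0.58 ± 0.056. Nephron and metanephric mesenchyme genes had a median of 0.027 (0.030 on array 1 and -0.032 on array 2, adjusted p = 0.800), with Gdnf at -0.56 ± 0.16 and Six2 at -1.12 and -0.22, with -0.012 ± 0.64 and -0.14 ± 0.047 at its other probes. Medians of the NOTCH, endothelial, proliferation, p53, hypoxia and amino acid stress lists were -0.011, -0.0067, -0.053, 0.020, 0.0099 and -0.064 (adjusted p = 0.800, 0.800, 0.0920, 0.231, 0.883 and 0.499). The medians turned between array 1 and array 2 for the NOTCH (-0.030 and 0.051), endothelial (0.063 and -0.13) and hypoxia lists (0.013 and -0.035). They were -0.099 and -0.0095 for proliferation, 0.093 and 0.037 for p53, and -0.010 and -0.016 for amino acid stress. The proliferation list was called lower after median centring (adjusted p = 0.00114) and without the filter on dim probes (adjusted p = 0.0237). The nephron list's camera direction was down and its median above 0, the endothelial list's camera direction was up and its median below 0, and the mean of the NOTCH list was above 0 and its median below. No member of these lists passed over all genes or adjusted over the list alone. Over all 26 lists, 14 were called, 5 higher and 9 lower, and 0 were called with an estimated correlation or by fry (lowest adjusted p = 0.187). Camera with an estimated correlation could hardly call a list, as it rests on 1 residual degree of freedom. With array 2 left unturned, 0 lists were called.

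**Figure D3:**
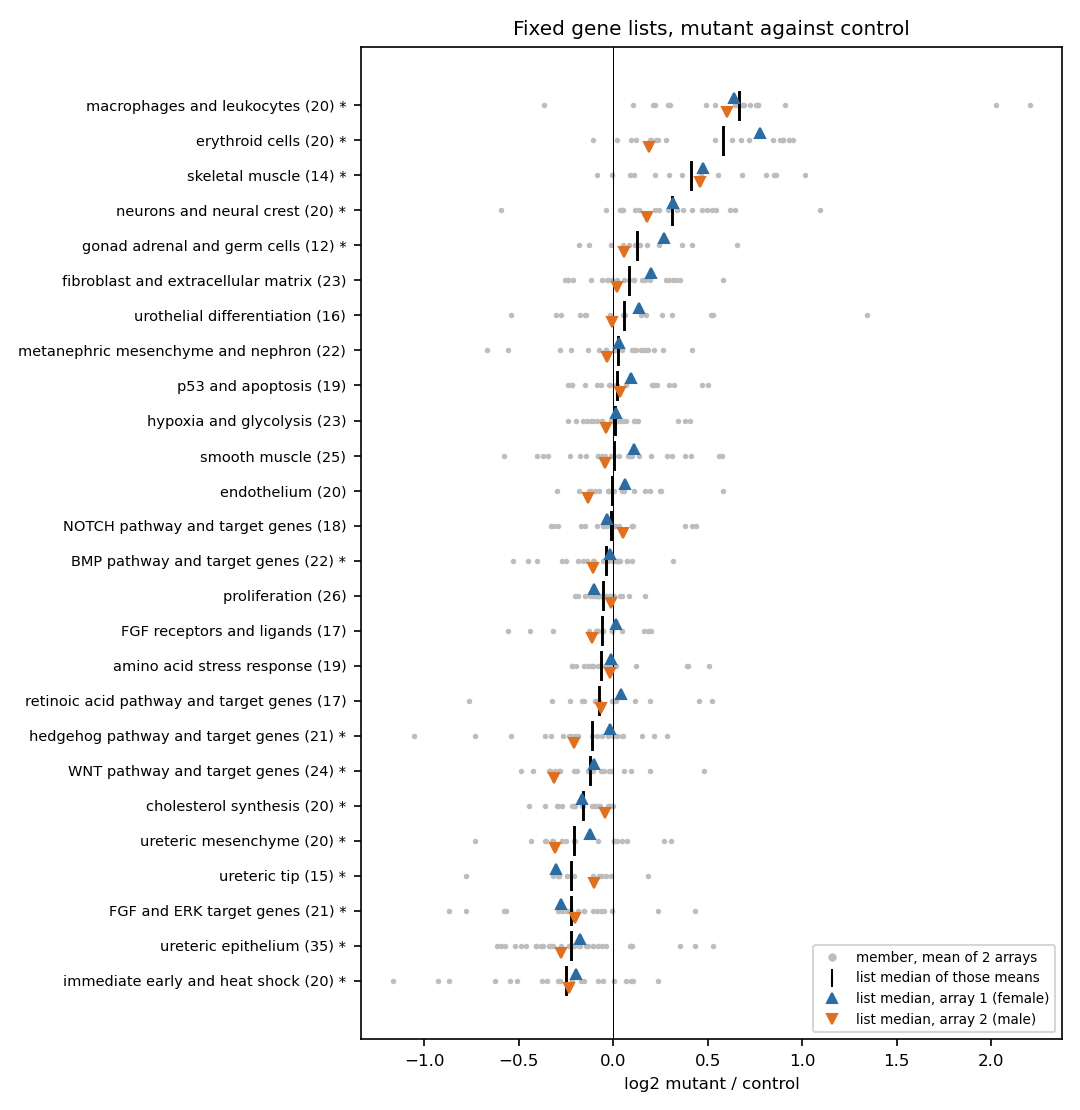
Log2 mutant over control of the members of the 26 lists (grey, mean of both arrays; measured number in parentheses), with the list median as a black bar and the medians of array 1 and array 2 as triangles; an asterisk marks a camera adjusted p under 0.05. The macrophage and leukocyte list has the highest median, 0.67, and the immediate early list the lowest, -0.25.

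The arrays differ in the sex of the pools and in the dye of the mutant RNA at once, so values of the 2 arrays can be set side by side but their difference cannot be tested. On array 1, 399 genes differed at least 1.5-fold between mutant and control, and on array 2, 1440 genes. The SD of the ratios was 0.208 on array 1 and 0.325 on array 2.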

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

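The 20 genes that differed at least 1.5-fold in opposite ways on the 2 arrays were singled out because the female and the male pair of pools moved in opposite directions. The difference was not tested, since each sex has 1 array and sex goes with the dye orientation. Simulated sets gave a mean of 58.6 such genes. Their spread was fitted to the difference between the 2 arrays, which holds dye and sex, so they cannot decide whether the observed number is above chance. Of the 20 genes, 19 were higher in the mutant on array 1 and lower on array 2, and 1 was the other way round. The only member of a fixed list among them was Vwf, an endothelial clotting factor, at 1.56 on array 1 and -1.33 on array 2.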

How the results depend on the processing

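The count of 6 called genes was 13 with a normexp offset of 16 and with processed signals, 14 with an intensity trend, and 12 with probes well above background in both groups, each with all 6 genes kept. It was 0 after median centring (853 at an unadjusted p under 0.05), without the filter on dim probes (1076) and with no replicate block (428). It was 2 with other tissues' marker genes left out, an alternative chosen after seeing the data, which removes called genes by construction. It lay between 4 and 9 under the other settings. The 82 genes that differed at least 1.5-fold the same way became 16 at 2-fold, 231 with processed signals and 208 with the authors' table. Opposite-way genes rose with them, to 119 and 91, and median centring gave 78 (41 higher, 37 lower) with 67 opposite. The median ratio of all tested genes was -0.084 under median centring, a shift toward lower ratios. With 1 array alone the count was 399 to 1440. Elsewhere it lay between 65 and 100. The 14 called lists became 0 with an estimated correlation and 0 with fry, both set before the data were examined, and 9 without other tissues' markers, where the 5 higher lists are emptied by construction. The setting with an estimated correlation rests on 1 residual degree of freedom, so it could hardly call any list. Other settings gave 13 to 15. For calls of genes and lists, 1 array allows no test, and the fold count has no value of its own with the channels fitted separately. Leaving out saturated probes removed none. Unless construction is named, the cause was not tested.

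Among named genes, the sign of Ddx3y (0.011) turned with no background correction (-0.0079), offset 16 (-0.0089), processed signals (-0.034), median centring (-0.095) and the authors' table (-0.069), and that of Fgfr1 (-0.084) turned with the mean of its probes (0.061). Smooth muscle's median turned with median centring (-0.086), without a filter and with the filter on both groups (-0.0043 each) and with the authors' table (-0.0049). Median centring also turned the medians of the fibroblast (-0.085), nephron (-0.027), p53 (-0.028) and hypoxia (-0.13) lists, the authors' table that of hypoxia (-0.0027), and processed signals that of NOTCH (0.00021). Under median centring the median of all tested genes was itself -0.084. The smooth muscle and fibroblast medians lay at that shift, the nephron and p53 medians above it and the hypoxia median below it. With 1 array alone, medians turned for NOTCH (0.051), nephron (-0.032), hypoxia (-0.035), retinoic acid (0.041), FGF receptor (0.014), urothelial (-0.0079), smooth muscle (-0.045) and endothelial (0.063) lists. None of these was called. Over all settings, named genes past or short of the threshold crossed it upward in 29 and downward in 17 comparisons, and list medians in 2 and 6. The BMP call was lost under 5 settings and the gonad call under 1. Signal over background limits dim genes, whose ratios shrink with the offset.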

Other observations

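Some genes outside the 26 lists fixed in advance, named after their values were seen, were higher on both arrays without passing limma's adjusted p. Camp, an antimicrobial peptide of neutrophil granules, was at 1.16 and 1.38 (adjusted p = 0.0886), Nefm, a neurofilament subunit, at 1.22 and 1.32 (adjusted p = 0.0781), and Apela, a small secreted peptide, at 1.22 and 1.19 (adjusted p = 0.0922), and Camp passed under 2 and Nefm under 3 alternatives. Camp is also 1 of the granulocyte genes used below. Around Hoxb8, its neighbours in the cluster were less far from 0, with Hoxb7 at -0.059 and -0.27 and Hoxb9 at -0.13 and -0.91.

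All tests below, their gene lists and the genes named from these were chosen after the results they weigh were seen, and genes are not independent replicates in them. Liver, blood and muscle markers were higher in the mutant pools. All 14 measured hepatocyte genes were higher on both arrays, with medians of 0.90 on array 1 and 0.18 on array 2, and Alb and Afp at 1.60 and 0.45, and 2.22 and 0.78. Leukocyte markers lay above endothelial markers by 0.67 in the median (permutation of genes, two-sided p = 3e-05). Both medians were known when this pair was chosen, so the contrast cannot decide whether a lower share of ureteric cells explains the pattern. Of 11 granulocyte genes (medians 0.44 and 0.75, 2 of them also in a list fixed before), 8 were higher on both arrays. Those medians were the values of Csf3r and Itgam, at log2 levels of 14.4 to 16.3, against 9.23 to 11.7 for S100a9. From array 1 to array 2, which differ in sex and dye at once, the median change per gene was 0.22 for granulocyte and -0.65 for hepatocyte genes. These median changes differ by 0.87. So a lower share of ureteric cells and 1 source of liver tissue may each contribute. More leukocytes in mutant ureters (17 of 20 markers higher on both arrays) and several kinds of neighbouring tissue carried over in dissection may contribute as well. These explanations cannot be told apart, as all go with the pools.

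Prm1 was 10.2-fold higher in the mutant pools. The median of 9 other spermatid genes was -0.047, which argues against spermatid transcripts as its source and does not test other germ cells. These 9 genes were dim, at normalised log2 levels from 6.69 to 7.70, where ratios shrink. A dye bias is argued against by the lower of both ratios, 2.79, with the dyes exchanged. A protamine sequence in the Cre transgene may be the source of the 3.36 ratio, as a hypothesis only: the sequence of the construct was not analysed here. No other biological explanation was tested.

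Xist was higher in the control than in the mutant RNA of the male array. A dye bias is argued against, since no Xist probe exceeded 0.034 in absolute ratio on the female array. Set against the female array in the same dye, Xist stood at 16.9% in the male control and 5.42% in the male mutant RNA. Female tissue in the male control pool may be the source, and it needs Y-linked genes at 0.19, mutant over control. Ddx3y was at 0.31 and Eif2s3y at -0.30, and the probes dim on the female array were at 0.16 and -0.45 (Uty) and -0.086 (Kdm5d), on both sides of that value, so that the explanation stays open.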
